A study of Mus musculus with 30 samples.

How the data were processed

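The series holds 30 samples of E14Tg2A mouse embryonic stem cells grown in serum and LIF. Peak lists of 20 ChIP samples were used, and the 9 RNA samples and the IgG sample were not used here because no file of theirs was at hand. Per the labels' protocols, EPOP was depleted with lentiviral short hairpin RNA and EloB with small interfering RNA. EloB ChIPs had an added protein crosslinking step, and the EloB and EPOP replicates differed in antibody or antibody lot, with the same antibody in the same-numbered replicate of both conditions. Groups and replicate numbers were taken from the sample titles, which do not tie a list without knock-down to the hairpin or the small interfering RNA. Per the file headers the 2 lists of Suz12 and of H3K4me3 are named for different methods, and both were used as lists without knock-down for each comparison. The labels do not say that replicates were separate cultures, so the spread between them may be technical.

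Bowtie, TopHat and Cufflinks and the mouse build mm9 are named in the submitters' processing notes, without roles or versions. The peak caller is not given in the sources used here, apart from peak names that carry MACS per the file headers and names. Each list gives a chromosome, a start, an end and a score for each peak; the deposited score is the authors' own value, at least 50 in every list, and its definition is not given in the sources used here. The score was used to rank and filter peaks, to describe missing, kept and flanking regions and to group or match regions; where 2 lists were at hand, missing and kept regions were described by the highest score over both. Lists belong to 1 sample each, so no list is named as pooled. Coordinates are mm9 and are given counted from 1.

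Reference regions of a target were the merged peaks of the lists without knock-down that overlapped a peak of the other list by at least 1 bp, or all peaks where there was 1 list. A region was kept if it overlapped a knock-down peak by at least 1 bp, and missing otherwise; a knock-down peak was new if it overlapped no peak of any list without knock-down. Shares carry Wilson 95% intervals, which cover counting of regions only. Width change was the median over kept regions of the log2 ratio of summed peak width to the mean over lists without knock-down, with bootstrap intervals from 2000 resamples. A peak that overlapped several regions was counted in full for each of them. Peak number was tested by a two-sided exact permutation test where both conditions had 2 lists. The difference in width change between EPOP-bound and EPOP-free Suz12 regions was tested with 100000 permutations of regions (10000 in the alternatives).

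Co-occupancy was tested with two-sided Fisher's exact tests over the H3K4me3 regions, with Benjamini-Hochberg adjustment over 7 tests, and beside it regions were shifted around their chromosomes 1000 times. EPOP-bound means overlap with an EPOP region of both replicates. Regions were named by a rule: for each comparison the 5 missing and the 5 kept regions with the highest score in replicate 1 and the 5 new peaks with the highest score, of which some are printed. The groups, tests, naming rule and processing alternatives were set before the data were examined. The splits of EloB regions, Jarid2 gains and H3K27me3 regions by EPOP or Suz12, the counts by chromosome, the flanks of missing regions and the overlaps of new peaks were added after the data were seen. The alternatives were the higher-scoring part of each list, overlap of at least 0.5 of the shorter peak, and a distance of up to 1000 bp. Others were lists of equal length, regions of either list, covered length, autosomes and X alone, each replicate left out, and ratios within replicate numbers. The higher-scoring part held peaks at or above the median score of all peaks in the target's lists without knock-down. The same cut was applied to knock-down lists, so lists with lower scores lost more peaks. For lists of equal length, each target's lists were cut by score to its shortest list, knock-down lists included, so lengths still differed between targets.

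Lists of genes had also been fixed to be tested at promoters, but no mm9 gene annotation was used here, so these tests were not run and no gene is assigned to a peak. Depth per sample is unknown, and peaks called separately in each list depend on it, so a missing peak does not measure how much signal was left. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Matplotlib 3.10.9 and bedtools 2.31.1. The overlap code matched bedtools in all 400 pairs of the 20 lists. It was also tested on simulated data: over 5720 simulated EPOP regions the kept share was recovered within 1.87 percentage points and the log2 width ratio within 0.028, and over 32277 H3K4me3 regions a true odds ratio of 5 was recovered as 5.42.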

Results

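EPOP (also C17orf96), a protein that associates with Polycomb repressive complex 2 (PRC2), was studied in E14Tg2A cells, a male mouse embryonic stem cell line, by chromatin immunoprecipitation and sequencing (ChIP-seq). Peak lists of 20 ChIP samples were analysed for 6 targets: EPOP, Elongin B (EloB, a subunit of the elongin complex), Suz12 (a core subunit of PRC2), Jarid2 (an accessory subunit of PRC2), H3K27me3 (the histone mark that PRC2 deposits) and H3K4me3 (a mark of promoters). EPOP and EloB had 2 lists without knock-down and 2 upon EPOP knock-down. Suz12 and H3K4me3 had 2 lists without knock-down, 1 upon EPOP knock-down and 1 upon EloB knock-down. Jarid2 and H3K27me3 had 1 list in each of the 2 conditions, without replicates. The 9 RNA samples and the IgG sample of the series were not analysed here. Read depth is unknown for every list, so all comparisons concern the presence, number and width of peaks.

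The first comparison asked whether the EPOP ChIP signal depended on EPOP. The lists without knock-down held 11072 and 6547 EPOP peaks (8809.5 ± 3199.7, SD, n = 2), and those upon EPOP knock-down held 108 and 818 (463 ± 502, SD, n = 2). Of 5720 EPOP regions found in both lists without knock-down, 0.839% (Wilson 95% interval 0.634 to 1.11) overlapped a peak of knock-down replicate 1 and 8.88% (8.17 to 9.65) a peak of replicate 2. The mean of the 2 was 4.86%, and 17.6% with lists of equal length (the 108 highest-scoring peaks of each). It was 0.560% with the higher-scoring part of each list and 2.70% with regions of either list. With replicate 1 as the only list without knock-down it was 2.55%. The ratio of mean peak number was 0.0526, and 0.0084 with the higher-scoring part. Between the lists without knock-down, 92.0% of the replicate 2 peaks overlapped a replicate 1 peak and 53.2% of the replicate 1 peaks overlapped a replicate 2 peak. The EPOP regions still found were narrower, with a median log2 width ratio of −2.52 in replicate 1 (48 regions) and −1.75 in replicate 2 (508 regions). They were also among the strongest, with median score percentiles of 94.0 and 90.9 among the 5720 EPOP regions.

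Among the highest-scoring EPOP regions with no knock-down peak was chromosome 4, 48055325 to 48065953 (mm9), 10629 bp wide, which held a peak in 16 of the 20 lists. Others were chromosome 6, 85135660 to 85142557, and chromosome 18, 64497150 to 64506763. Among those still found were chromosome 19, 44822542 to 44837120, and chromosome 5, 33770935 to 33781440, each with a peak in 18 of the 20 lists. A two-sided exact permutation test of peak number gave p = 0.333, the smallest that 2 lists against 2 allow. For knock-down replicate 1 the labels conflict, since its description names IgG while its title and antibody name EPOP. The description of the IgG sample in turn names C17orf96, so a swap of these libraries cannot be excluded. The title was followed here, so the values of replicate 1 are those of the library titled EPOP knock-down. Replicate 2, in which 8.88% of EPOP regions were kept, has no such conflict.

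**Figure D1:**
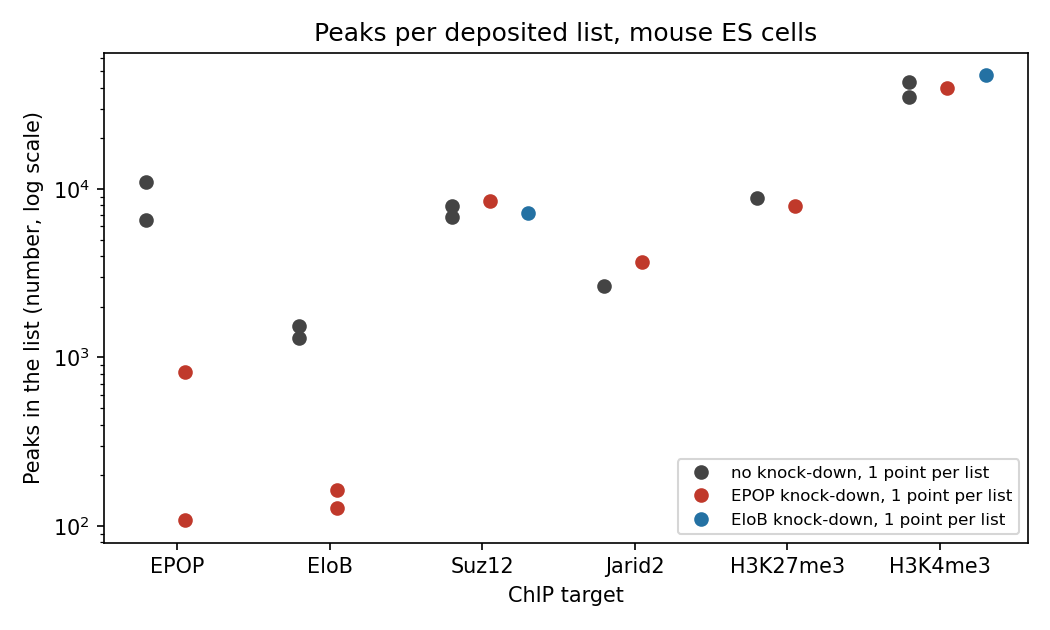
Number of peaks in each deposited list (log scale) by ChIP target, with 1 point per list, coloured by knock-down. EPOP lists fell from 11072 and 6547 peaks to 108 and 818 upon EPOP knock-down, and EloB lists from 1296 and 1542 to 164 and 127.

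The next question was where EPOP lay relative to PRC2 and elongin. EPOP regions lay largely on polycomb regions: 89.8% (Wilson 95% interval 89.0 to 90.5) overlapped Suz12, 84.4% (83.4 to 85.3) H3K27me3, 40.6% (39.4 to 41.9) Jarid2 and 13.3% (12.4 to 14.2) EloB. Of the 5720 EPOP regions, 5489 overlapped H3K4me3. EloB regions, 930 in number, lay on EPOP in 90.4% (88.4 to 92.2), on Suz12 in 91.9%, on Jarid2 in 91.6% and on H3K27me3 in 91.5%. Shifting the regions around their chromosomes 1000 times left at most 2.26% of EPOP regions on Suz12 and at most 3.55% of EloB regions on EPOP. EPOP regions that carried EloB were wider (median 3897 bp against 2061 bp) and had higher scores (median 1584 against 283). Of them 98.7% overlapped Jarid2, against 31.7% of those without EloB. These classes were not matched on score, so a link of EloB to Jarid2 was not told apart from EloB detection at the strongest regions.

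Over the 32277 H3K4me3 regions, EPOP was found at 81.6% of the 6084 that also carried H3K27me3 and at 3.17% of the 26193 that did not. H3K4me3 regions with Suz12, H3K27me3 and Jarid2 carried EPOP in 99.3% and EloB in 33.4% (31.6 to 35.3) of 2446 regions. Those with Suz12 and H3K27me3 but without Jarid2 carried EPOP in 86.4% and EloB in 0.489% (0.286 to 0.835) of 2657 regions. These classes were not matched on peak strength. The odds ratio of co-occupancy was 300.04 for EPOP with Suz12 (95% interval 268 to 336), 228 for EPOP with Jarid2 (184 to 283), 136 for EPOP with H3K27me3 (124 to 149) and 84.8 for EPOP with EloB (64.0 to 112). For EloB it was 95.3 with Suz12 (70.2 to 129), 265 with Jarid2 (200.1 to 352) and 84.5 with H3K27me3 (63.3 to 113). All 7 two-sided Fisher's exact tests gave p-values below the smallest number the software can hold, before and after Benjamini-Hochberg adjustment. With EPOP replicate 1 as the only EPOP list the odds ratios with Suz12, Jarid2, H3K27me3 and EloB were 145, 125, 61.8 and 41.8, and with EloB replicate 1 as the only EloB list those of EloB with Suz12, Jarid2 and H3K27me3 were 51.5, 125 and 47.5. EPOP with EloB gave 49.9 with EloB replicate 1 alone and 130 with replicate 2 alone, EloB with Suz12 149 with EloB replicate 2 alone, and EPOP with Suz12 186 with Suz12 replicate 2 alone. With regions of either list EPOP gave 102 with Suz12, 195 with Jarid2, 80.6 with H3K27me3 and 49.2 with EloB. With the higher-scoring part of each list EPOP gave 626 with Jarid2 and 440 with Suz12. The order of Suz12 and Jarid2 thus turned in both of these settings, and with Suz12 replicate 2 alone. With lists of equal length EPOP gave 977 with Suz12, 984 with H3K27me3 and 369 with EloB. EloB then gave 60.3 with Suz12, 157 with Jarid2 and 42.1 with H3K27me3. In that setting EPOP lists were cut to 108 peaks and EloB lists to 127, so these ratios rest on their highest-scoring peaks. Regions near each other are not independent, so these tests describe the lists rather than repeated experiments.

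The EPOP lists without knock-down differed in what they added to the shared regions. The 5177 peaks of replicate 1 with no counterpart overlapped H3K4me3 in 81.2% and Suz12 in 13.4%, and 0.0579% (0.0197 to 0.170) overlapped EloB. The 526 peaks of replicate 2 alone overlapped H3K4me3 in 47.0% and Suz12 in 36.3%.

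EloB occupancy was compared next, to see whether it depended on EPOP. EloB lists fell from 1296 and 1542 peaks (1419 ± 174, SD, n = 2) to 164 and 127 (146 ± 26.2, SD, n = 2) upon EPOP knock-down. Of 930 EloB regions, 7.74% (Wilson 95% interval 6.19 to 9.64) overlapped a peak of knock-down replicate 1 and 6.67% (5.24 to 8.45) a peak of replicate 2. EPOP-bound EloB regions were nearly all missing, with 2 and 3 of 841 kept (0.238% and 0.357%). EPOP-free EloB regions were mostly kept, with 70 of 89 (78.7%, 69.0 to 85.9) in replicate 1 and 59 of 89 (66.3%, 56.0 to 75.3) in replicate 2.

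Among the missing EloB regions were chromosome 5, 33772730 to 33778184, which held a peak in 18 of the 20 lists, chromosome 1, 42752468 to 42756354, and chromosome 13, 31897619 to 31901073. The kept EloB regions with the highest scores were chromosome 1, 46909816 to 46911127, and chromosome 9, 78320451 to 78326400, each with a peak in 8 of the 20 lists, and the start of the mitochondrial sequence. EPOP-bound EloB regions overlapped Suz12 in 100% and Jarid2 in 98.8%, and EPOP-free ones in 15.7% and 23.6%. H3K4me3 was overlapped by 98.0% of the EPOP-bound and 57.3% of the EPOP-free ones. The number of EloB peaks gave p = 0.333 in the two-sided exact permutation test, again the smallest possible. The split by EPOP was chosen after the values were seen: its odds ratio of being kept, EPOP-free over EPOP-bound, was 1546 (353 to 6771) and 549 (163 to 1853), with adjusted p = 3.06e-84 and 2.01e-66 over 4 two-sided Fisher's exact tests. With an EPOP peak in either replicate counted as bound, 56 and 35 of 65 EPOP-free regions were kept, and 16 and 27 of 865 EPOP-bound ones. The odds ratio was then lower, at 330 (140 to 780) and 36.2 (19.5 to 67.3).

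**Figure D2:**
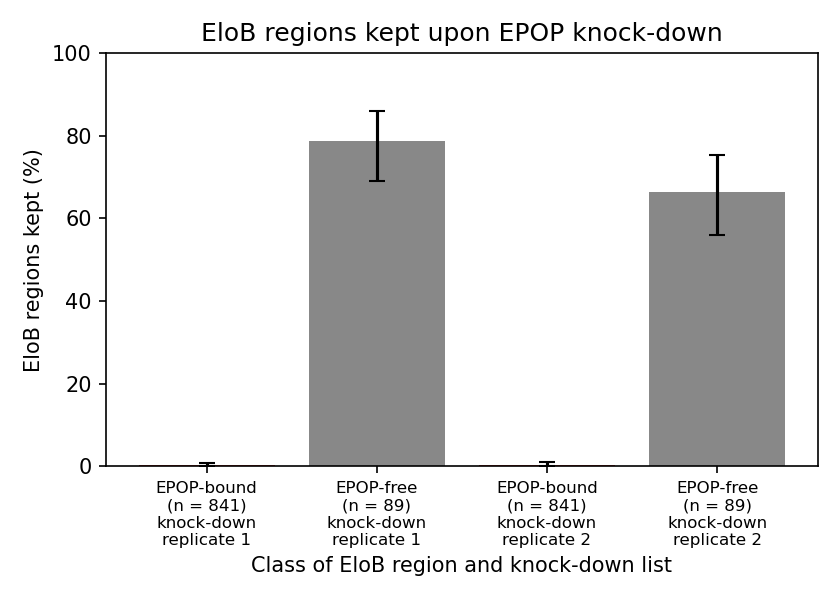
Percentage of EloB regions that overlapped a peak of each knock-down list, for regions with and without an EPOP region, with Wilson 95% intervals as error bars. EPOP-bound regions (841) were kept in 0.238% and 0.357%, and EPOP-free regions (89) in 78.7% and 66.3%.

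Suz12 was compared to see whether PRC2 stayed on chromatin without EPOP or EloB. Of 5669 Suz12 regions, 96.9% (Wilson 95% interval 96.4 to 97.3) overlapped a Suz12 peak upon EPOP knock-down and 97.7% (97.2 to 98.0) upon EloB knock-down. Of the replicate 1 and replicate 2 peaks without knock-down, 86.6% and 87.9% had a counterpart upon EPOP knock-down and 93.5% and 82.8% upon EloB knock-down, against 83.2% and 81.5% in each other's list. The Suz12 list held 8491 peaks upon EPOP knock-down and 7168 upon EloB knock-down, against 6834 and 7972 without (7403 ± 805, SD, n = 2). The EloB knock-down list thus lay within the range of the lists without knock-down, and the EPOP knock-down list above it by less than the gap between them.

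Suz12 peaks upon EPOP knock-down had a median log2 width ratio of −0.24 to replicate 1 and 0.13 to replicate 2 without knock-down, and upon EloB knock-down of 0.040 and 0.46. The lists without knock-down differed by −0.39 between themselves (replicate 2 over replicate 1), so no direction of width change held against both for EPOP knock-down. Per the file headers, Suz12 replicate 1 is named si ct and replicate 2 sh ct, so that gap need not be replicate spread alone; against the list named for its own method the ratio was 0.13 upon EPOP knock-down and 0.040 upon EloB knock-down. Against their mean, Suz12 regions bound by EPOP had a median of −0.077 (4764 regions) and EPOP-free ones −0.030 (729 regions) upon EPOP knock-down, with a difference of −0.046 (bootstrap 95% interval −0.069 to −0.016) and p = 1e-05 in a two-sided permutation test over regions, the smallest that 100000 permutations can give. That difference turned to 0.10 within quartiles of control width and was −0.0021 (p = 0.846, permutation test) with replicate 2 as the only list without knock-down. Upon EloB knock-down it was −0.030 (−0.064 to 0.0060; p = 0.0082, two-sided permutation test) and was −0.080 (−0.10 to −0.060; p = 0.0001, permutation test) with replicate 1 alone, the list named for its own method, and −0.057 (p = 0.0034, permutation test) within quartiles of control width. It turned to 0.069 with replicate 2 alone and to 0.016 with the higher-scoring part of each list, so neither difference kept 1 direction in every setting.

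Missing Suz12 regions were weak, with a median highest score of 115 upon EPOP knock-down against 1129 for those kept. An exception upon EloB knock-down was chromosome 11, 96129226 to 96216942, 87717 bp wide, which held a peak in 16 of the 20 lists. In that list no peak lay between 96126781 and 96224601, while the peaks on either side had scores of 1109 and 3100; without reads it was not checked whether signal or only a called peak was absent. New Suz12 peaks numbered 1175 upon EPOP knock-down, among them chromosome 2, 19579336 to 19580538, and 613 upon EloB knock-down. The new peaks upon EPOP knock-down were narrow (median 840 bp), 89.0% overlapped H3K4me3 and 8.85% H3K27me3. The 1473 Suz12 peaks of replicate 2 alone without knock-down had a median of 791 bp, with 73.2% on H3K4me3 and 12.6% on H3K27me3, and the 1145 of replicate 1 alone had a median of 1122 bp, with 61.7% and 42.9%.

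Jarid2 was compared upon EPOP knock-down in 1 list per condition. The lists held 2641 peaks without and 3665 with knock-down, and 96.9% (Wilson 95% interval 96.2 to 97.5) of Jarid2 regions were kept. The 1225 new Jarid2 peaks lay on Suz12 regions in 94.3%, on EPOP regions in 90.0% (97.0% of the kept regions did so) and on H3K27me3 regions in 84.0%. Jarid2 peaks at kept regions were wider, with a median log2 ratio of 0.31 (bootstrap 95% interval 0.29 to 0.32), and 89.3% of the 2559 regions widened. Of Suz12 regions, 38.3% (37.0 to 39.6) overlapped Jarid2 without and 56.1% (54.8 to 57.4) with EPOP knock-down.

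New Jarid2 peaks with the highest scores included chromosome 8, 124806249 to 124809344, chromosome 17, 25568864 to 25571179, and chromosome 16, 15886335 to 15889075. Among Suz12 regions without Jarid2 before, 37.1% (35.3 to 39.0) of the 2678 EPOP-bound and 6.46% (4.98 to 8.36) of the 820 EPOP-free ones held a Jarid2 peak upon knock-down. Of all Suz12 regions, those with Jarid2 went from 44.4% to 64.4% where EPOP-bound and from 3.76% to 9.27% where EPOP-free. The odds ratio of a gain was 8.54 (6.40 to 11.4), with p = 2.44e-76 in a two-sided Fisher's exact test over regions, chosen after the values were seen. With 1 list per condition the difference has no replicate check and compares these libraries. EPOP-bound and EPOP-free regions were not matched on strength, so a better-yielding knock-down list could not be told apart from a gain tied to EPOP. With lists of equal length, 89.2% of Jarid2 regions were kept.

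H3K27me3 was also compared in 1 list per condition, to see whether the mark set by PRC2 followed EPOP. The lists held 8811 peaks without and 7956 with EPOP knock-down, while the covered length was 16.8 Mb without and 18.4 Mb with knock-down. Of H3K27me3 regions 77.0% (Wilson 95% interval 76.1 to 77.9) were kept: 91.9% (91.2 to 92.6) of the 6219 on Suz12 and 41.1% (39.2 to 43.0) of the 2592 off Suz12. The class off Suz12 was also narrower (median 887.5 bp against 1839 bp), and the classes were not matched on strength. With 1 list per condition, a loss off Suz12 was not told apart from weaker regions missing a called peak. Kept regions were wider, with a median log2 ratio of 0.42 (bootstrap 95% interval 0.39 to 0.44) in 6783 regions. A knock-down peak that spanned several regions was counted in full for each, which raises this ratio where neighbouring peaks merged. The ratio was 0.21 with peaks up to 1000 bp apart counted as overlapping, where neighbouring peaks without knock-down were summed too. EPOP-bound H3K27me3 regions had a median of 0.40 and EPOP-free ones of 0.55.

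The ratio of H3K27me3 peak number had no stable direction: it was 0.903, and 1.06 with the higher-scoring part of each list. Among the missing H3K27me3 regions with the highest scores, all 5 lay in 2 stretches, chromosome 15 from 102777068 to 102849481 and chromosome 11 from 96127558 to 96197862. In those stretches the knock-down list held no peak, while its flanking peaks scored 417 and 137, and 791 and 845; here too no reads were at hand to tell absent signal from an absent call. The stretch of chromosome 11 overlaps the one that the Suz12 list upon EloB knock-down lacked. Such cases were few, as 9 of the 882 regions with the highest scores were missing, and the missing regions had a median score of 66.7 against 162 for those kept.

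H3K27me3 peaks on chromosome X numbered 90 without and 202 with EPOP knock-down, a log2 ratio of 1.17, while the 19 autosomes ranged from −0.42 to 0.019. Relative to autosomes the X peak number rose 2.52 times (95% interval 1.97 to 3.24; adjusted p = 5.46e-13, two-sided Fisher's exact test over peaks of 1 list per condition) and the covered length 2.86 times. Between the EPOP lists without knock-down the X peak number relative to autosomes also differed. The ratio was 1.42 (1.13 to 1.79, adjusted p = 0.0199, two-sided Fisher's exact test over peaks, replicate 2 over replicate 1) and 1.48 in covered length. The same ratio of peak number was 0.975 (0.796 to 1.19) between the Suz12 lists and 1.02 (0.926 to 1.11) between the H3K4me3 lists. Of 136 Suz12 regions on X, 35.3% (27.8 to 43.6) overlapped H3K27me3 without and 72.8% (64.8 to 79.6) with knock-down. Of 5532 Suz12 regions on autosomes, 83.8% (82.8 to 84.8) and 83.6% (82.6 to 84.6) did so. New H3K27me3 peaks on X with high scores were 101015025 to 101017776 and 99044845 to 99047270.

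**Figure D3:**
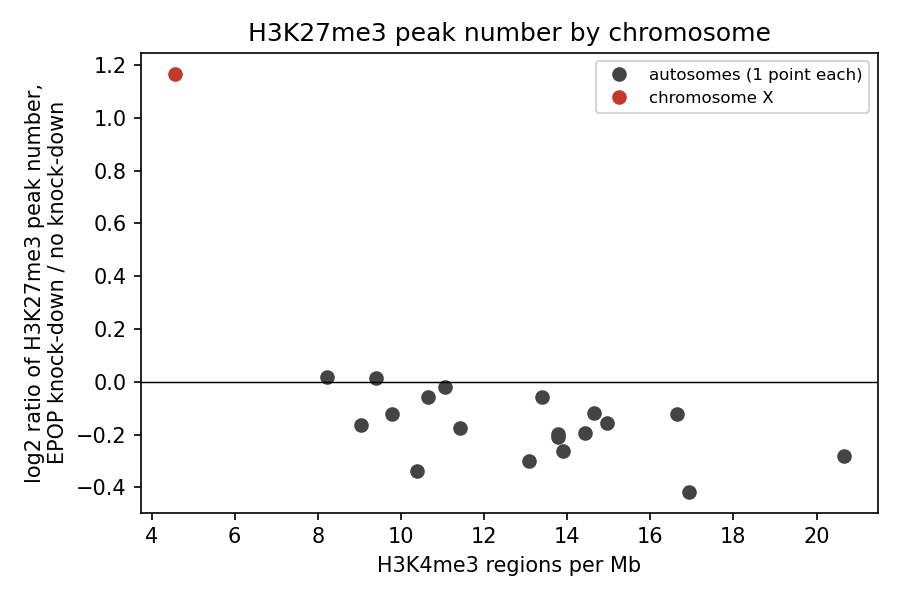
Log2 ratio of H3K27me3 peak number (EPOP knock-down over no knock-down) against H3K4me3 regions per Mb, with 1 point per chromosome. Chromosome X lies at 1.17 and the 19 autosomes lie between −0.42 and 0.019.

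H3K4me3 was compared to see whether the promoter mark changed. Of 32277 H3K4me3 regions, 96.1% (Wilson 95% interval 95.9 to 96.3) were kept upon EPOP knock-down and 99.0% (98.9 to 99.1) upon EloB knock-down. The lists held 39967 peaks upon EPOP knock-down and 47296 upon EloB knock-down, against 35027 and 42857 without (38942 ± 5537, SD, n = 2). H3K4me3 peaks upon EloB knock-down were wider than in either list without knock-down, with median log2 ratios of 0.22 to replicate 1 and 0.052 to replicate 2. Upon EPOP knock-down they were 0.11 and −0.051, and the lists without knock-down differed by 0.16. Per the file headers, H3K4me3 replicate 1 is named sh ct and replicate 2 si ct, so this gap too need not be replicate spread alone.

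New H3K4me3 peaks numbered 2522 upon EPOP knock-down and 6614 upon EloB knock-down, and 0.595% and 1.47% of them overlapped an EPOP region. The new peaks with the highest scores were chromosome 11, 88842118 to 88843747, upon EPOP knock-down and chromosome 11, 100823189 to 100826124, upon EloB knock-down. Missing H3K4me3 regions were weak, with median highest scores of 103 and 87.0 against 1012 and 927 for those kept. The change in H3K4me3 peak number and width upon EPOP knock-down was smaller than the gap between the lists without knock-down. No test across samples was run for H3K4me3.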

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

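Over 31 results and 250 alternatives, 199 kept their direction and stayed within the spread or on the same side of the threshold; the others are given here, and the cause of each change was not tested. For EPOP and EloB peak number the exact permutation test cannot reach the threshold, so only a change of direction could be counted. For co-occupancy all tests stayed far below the threshold, so shifts in the size of an odds ratio were not counted. The splits of EloB regions by EPOP and the removal of regions in EPOP knock-down lists were chosen after seeing the data. With the higher-scoring part of each list, kept shares were 5.66% (EloB), 98.7% and 99.6% (Suz12 upon EPOP and EloB knock-down), 99.1% (Jarid2) and 88.8% (H3K27me3). Peak number ratios were then 1.17 (Suz12, EloB knock-down), 1.62 (Jarid2), 1.06 (H3K27me3) and 0.961 (H3K4me3, EPOP knock-down), log2 widths 0.23 (Jarid2) and 0.32 (H3K27me3), and the EPOP-bound minus EPOP-free Suz12 difference upon EloB knock-down 0.016 (p = 0.398, permutation test). With half-length overlap, H3K27me3 gave 73.6% kept and a width of 0.36. Within 1000 bp, kept shares were 8.33% (EloB) and 81.2% (H3K27me3), widths 0.27 (Jarid2) and 0.21 (H3K27me3), and the Suz12 difference upon EloB knock-down −0.022 (p = 0.0869, permutation test). Covered length gave ratios of 0.985 and 1.19 (Suz12, EPOP and EloB knock-down), 1.53 (Jarid2) and 1.09 (H3K27me3). Regions of either list gave 5.63% (EloB), 80.1% and 80.0% (Suz12) kept. Lists of equal length gave 17.6% (EPOP), 10.4% (EloB), 95.3% (Suz12, EPOP knock-down), 89.2% (Jarid2) and 80.7% (H3K27me3) kept, an H3K27me3 width of 0.39 and a Suz12 difference upon EPOP knock-down of −0.0032 (p = 0.915, permutation test); within quartiles of control width that difference was 0.10.

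Leaving out 1 replicate at a time gave EPOP peak number ratios of 0.0123 (without knock-down replicate 2) to 0.0929 (without knock-down replicate 1) and 5.35% to 7.74% of EloB regions kept, and for Suz12 upon EPOP knock-down 86.6% to 87.9% kept, widths of −0.25 to 0.16 and EPOP-bound minus EPOP-free differences of −0.057 to −0.0021. For Suz12 upon EloB knock-down the ranges were 0.899 to 1.05 in peak number, 82.8% to 93.5% kept, 0.045 to 0.55 in width and −0.10 to 0.069 in the difference. H3K4me3 upon EPOP knock-down ranged from 0.933 to 1.14 in number and from −0.045 to 0.12 in width. The direction turned without replicate 1 of the lists without knock-down for Suz12 width (EPOP knock-down), the Suz12 difference (EloB knock-down) and H3K4me3, and without replicate 2 for Suz12 number (EloB knock-down). EloB regions kept were 0.297% (EPOP-bound) and 72.5% (EPOP-free) with EPOP regions of both replicates, 2.49% and 70.0% with a peak of either, and 8.40% without regions in an EPOP knock-down list.

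Same-numbered EPOP and EloB lists share an antibody in the labels, so ratios within them (a replicate block) were taken: 0.0349 and 4.38% for EPOP peak number and regions kept, and 0.102 and 6.84% for EloB, with no change of direction. The tests of fixed gene lists at promoters, with their windows and stricter lists, were not run, since no mm9 annotation was used here. Depth is unknown for every list and limits every statement on missing, new or narrower peaks.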

Other observations

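Tests of yield and of shared background for EloB, of weak regions for H3K27me3 on X and of Jarid2 width, and the removal of background regions from them, were chosen only after the result was seen. The lists also held a small set of regions found nearly everywhere. Of 51809 merged regions, 11 carried a peak in all 4 EPOP and EloB lists of EPOP knock-down, 7 of them on chromosome 9 and 1 on the mitochondrial sequence, and 0 of them overlapped an EPOP region of both replicates. Chromosome 2, 98506243 to 98507866, and chromosome 9, 35112407 to 35113527, were each found in 19 of the 20 lists. EPOP replicate 1 without knock-down held 0 peaks on the mitochondrial sequence and replicate 2 held 2.

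New Suz12 peaks upon EPOP knock-down lay on EPOP peaks of replicate 1 alone in 42.2% (496 of 1175), as did 37.2% of the Suz12 peaks of replicate 2 alone without knock-down and 31.7% of those of replicate 1 alone. New Suz12 peaks upon EloB knock-down did so in 29.9%.

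EloB regions were lost upon EPOP knock-down where EPOP was bound and kept where it was not. The tables argue against weak peaks falling below the threshold, since in the quartile of highest EloB scores at most 1% of EPOP-bound regions were kept, against 100% and 78.8% of EPOP-free ones. A low yield of the knock-down libraries that removed regions by strength alone would spare the strongest. EPOP-free regions of the lowest quartile were kept in 47.8% and 73.9%, far more than EPOP-bound regions of the highest. The EPOP-free share kept rose over the 4 quartiles in replicate 1, from 47.8% to 73.3%, 83.3% and 100%. In replicate 2 it was 73.9%, 60%, 38.9% and 78.8%. Score quartiles cannot test a low yield that left only unspecific binding, so that case stays open. The EPOP-free quartile kept least had 38.9% (20.3 to 61.4). Without regions that held a peak in an EPOP knock-down list, the lowest quartile held only 6 EPOP-free regions. Of these, 2 were kept in each list (33.3%, 9.68 to 70.0). The EPOP-free quartile kept least then had 31.25% (14.2 to 55.6), against at most 0.885% in any EPOP-bound quartile. Unspecific binding in every ChIP stays open for the kept regions by the bound set, an upper limit below 50% for all 4 targets. Of the 89 kept in either list, bound by EPOP or not, 40.4% (30.9 to 50.8) overlapped a peak of any EPOP list. The share was 31.5% (22.8 to 41.7) for Suz12, 32.6% (23.7 to 42.9) for Jarid2 and 29.2% (20.8 to 39.4) for H3K27me3. Only the limit for EPOP thus passed 50%. These overlaps concern other targets, so regions bound unspecifically in EloB ChIPs alone were not covered. For example, the kept region on chromosome 15, 79905310 to 79908115, held a peak in the 4 EloB lists and in no other list. The split itself did not rest on regions with a peak in an EPOP knock-down list. Without them 88.7% and 54.8% of 62 EPOP-free regions were kept, against 0% and 0.211% of 474 EPOP-bound ones. The rest of the 841 EPOP-bound regions still held a peak in an EPOP knock-down list. EloB peaks were nearly all missing there as well, since only 2 and 3 of all 841 were kept. A dependence of EloB on EPOP and a part played by polycomb regions apart from EPOP stay open too, since all 841 EPOP-bound regions overlapped Suz12, and of the 14 EPOP-free ones that did, 10 held a peak in all 4 EPOP and EloB knock-down lists.

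H3K27me3 peaks on X rose upon EPOP knock-down, in 1 library per condition. A composition bias that follows H3K4me3 density over the autosomes does not reach X, which lay 11.2 residual SDs above that line extended to its density, and peaks split into more pieces would not have raised the covered length 2.86 times. Polycomb occupancy did not rise alike upon EPOP knock-down. The highest X over autosome ratio of peak number for Suz12 or Jarid2 was 1.16 (0.823 to 1.63, Jarid2), against 2.52 for H3K27me3. In covered length the Jarid2 ratio was 1.31, against 2.86 for H3K27me3. Weak regions below the threshold of the list without knock-down stay open: autosomal Suz12 regions matched on Suz12 score gained at most 1.54 percentage points, against 37.5 (28.7 to 46.3) on X, but 84.3% and 81.8% of them already overlapped H3K27me3, which left room for 15.7 and 18.2. X differs between these libraries mainly because few X regions carried a peak without knock-down. Of H3K27me3 peaks, 1.02% lay on X without and 2.54% with knock-down. The share was 2.58% to 2.87% in the Suz12 lists, 2.08% and 2.40% for Jarid2 and 2.22% to 2.43% for H3K4me3. Without knock-down it was 0.617% and 1.04% for EloB, and 1.47% and 2.08% for EPOP. A difference between the cultures or libraries that affects X alone may thus be the cause and also stays open, as does an effect of EPOP on the mark itself.

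Jarid2 peaks were wider upon EPOP knock-down, in 1 library per condition. Within quartiles of score EPOP-bound regions on Suz12 widened more than EPOP-free ones, by 0.34 on the log2 scale (bootstrap 95% interval 0.18 to 0.38; 2481 bound and 27 free regions). Of the 27 EPOP-free regions, 10 held a peak in all 4 EPOP and EloB knock-down lists, and without them the difference was 0.30 (−0.073 to 0.43). Without regions that held a peak in an EPOP knock-down list it was 0.21 (−0.28 to 0.38; 1985 bound and 13 free regions). A better-yielding library that widens all peaks alike therefore stays open, as does an effect of EPOP on Jarid2.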
